A study of Mus musculus with 36 samples.

How the data were processed

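RNA from cultured mouse cells of 4 Irf8 genotypes (gWT, gKO, cWT and cKO) was sequenced on days 0, 3 and 6 of osteoclast differentiation, in 36 libraries with 3 to each of the 12 groups. Cells at days 3 and 6 had received 20 ng/ml M-CSF and 40 ng/ml RANKL, per the labels' protocols. Per the submitters' processing notes, the tools used were CASAVA 1.8.4, bcl2fastq 2.17.1, TopHat2 2.1.0, Partek and deepTools, with the mouse build mm9. Per the file headers, reads were mapped with TopHat, and RPKM values (reads per kilobase of gene model, scaled to the reads of the library) were computed for each gene with Partek. The same header lines state that 3 data sets were combined and that the annotation of the day 6 cKO and cWT libraries had been corrected. The gene annotation, the counting settings, the treatment of reads that match several genes and the strand of the libraries are not given in the sources used here. The deposited sample sheet gives 34510144 to 92548145 alignments per library (median 46799532), and RPKM values already divide by such a total. Read counts per gene were not at hand, so single and low RPKM values carry an unknown counting error.

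The authors also deposited a table per day with group means on a log2 scale, ratios between groups and q-values. Compared with the RPKM table, the authors' log2 group means equal the mean of log2(RPKM + 0.1) over the 3 libraries of a group, and each deposited ratio is the ratio of the corresponding geometric means. The q-values come from the authors' ANOVA per gene, per the sheet names, and the terms of that model are not given. A question mark stands in place of a q-value for genes with a single value in all libraries. Only the Irf8 ratios, one Irf8 q-value and the number of genes with a q-value under 0.05 were taken from these tables.

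All else was computed from the RPKM values as deposited, without further scaling between libraries. Values were transformed to log2(RPKM + 1), and genes with an RPKM of at least 1 in at least 3 libraries were kept, 11863 of 24950. The pseudocount of 1 draws the change of genes with low RPKM toward 0, so their fold changes are understated. One limma model (version 3.58.1 in R 4.3.3, with trend and robust variance moderation) of 12 group means was fitted to all 36 libraries. Its contrasts were gKO against gWT and cKO against cWT on each day, day 3 against day 0 and day 6 against day 3 in gWT and in cWT, and 5 differences of differences. The p-values of limma's moderated test were adjusted within a contrast by the Benjamini-Hochberg method and called under 0.05. Errors of log2 changes are limma standard errors, and errors of RPKM are SDs over the 3 libraries. Genes called in both the g set and the c set were counted by direction and compared with the overlap of independent lists by Fisher's exact test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.

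Gene lists, comparisons, tests, the alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. The 25 lists hold 610 genes and cover osteoclast effectors, positive and negative osteoclast regulators, the V-ATPase and lysosome, the interferon response, MHC class I and class II, complement and opsonins, macrophage identity, monocytes, inflammatory cytokines and inflammasomes. They also cover neutrophil granules, mast cells with basophils and eosinophils, dendritic cells, lymphocytes, erythroid cells with megakaryocytes, stromal and endothelial cells, progenitors, the cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, and stress with immediate early genes. The last list, of sex-linked genes, was reported but not tested as a list. The other 24 were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Members called were counted with p-values adjusted over all genes and adjusted over the list alone. Genes are named by rule. For each contrast of groups these are the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the groups. Up to 4 members of each list with a mean of at least 5 RPKM in either group were added by the size of their change, called or not. For differences of differences the 5 highest and 5 lowest called genes were taken. Predicted gene models, small RNAs, mitochondrial genes and sex-linked genes were left out of that ranking, and Irf8 and the sex-linked genes were reported in any case.

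The fit was tested on simulated data for gKO against gWT at day 0, with the real means and residual spread of 11863 genes. Of 50 genes per fold it called 30 at 1.2-fold, 48 at 1.5-fold, 49 at 2-fold and 50 at 4-fold. Of 11623 unchanged genes 10 were called (0.086%), camera called the shifted list of 40 genes, and it called 0 of 23 unshifted lists. Only means and spread were real, so false calls of correlated lists stay unknown. The 36 pairs of libraries within groups were checked for copies, using gene lengths of the GRCm38 annotation as an approximation for 24460 symbols (98%), and 0 pairs were identical. Gene order around Irf8 was taken from the same assembly, and no coordinates were used.

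Libraries carry replicate numbers, so the numbers were checked for pairing before any fit with them was compared. Deviations from the group means correlated above 0.1 for all 3 numbers in 2 of the 10 contrasts between groups, gKO against gWT at day 3 (0.126, 0.115 and 0.222) and gWT day 3 against day 0 (0.347, 0.186 and 0.142). A pairing in these would rest on the data alone, since the labels do not say what a number marks. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 RPKM, quantile normalization, fits of only the groups compared, the replicate number as a block across groups or within genotype, and leaving out each library in turn. Alternatives chosen after seeing the data were the data set as a term, the data set s alone at day 6, the exclusion of the 6 day 6 libraries labelled cWT and cKO, and the exchange of their labels. The data set of a library was read from the first letter of its name in the sample sheet. The mean of cWT and cKO was never set against that of gWT and gKO, because those sets differ in data set and in sex-linked genes.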

Results

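Gene expression was measured by RNA-seq in mouse bone marrow-derived macrophages (BMMs) taken through osteoclast differentiation in culture. BMMs at day 0 had received the growth factor M-CSF. Cells at day 3 (pre-osteoclasts) and day 6 (osteoclasts, the multinucleated cells that resorb bone) had received 20 ng/ml M-CSF and 40 ng/ml RANKL, the cytokine that drives this differentiation. Cells came from mice of 4 labelled genotypes of Irf8, a myeloid transcription factor known to restrain osteoclast formation. They are named gWT, gKO, cWT and cKO here as in the labels, which do not spell out the prefixes g and c. The 36 libraries formed 12 groups of 3, one for each genotype and day. Of the 24950 listed genes 11863 were tested. Across genes, libraries of one group correlated at r = 0.992 to 0.999 on the log2(RPKM + 1) scale, and the median residual SD was 0.086. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

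The knocked-out gene was examined first, as a check of the labels. Irf8 RPKM was 63.6 ± 2.61 (mean ± SD, n = 3) in gWT BMMs and 57.4 ± 1.45 in gKO BMMs, a log2 difference of -0.14 that did not pass (limma adjusted p = 0.259). It was 5.46 ± 0.493 in gWT and 13.4 ± 1.16 in gKO at day 3, higher in gKO by 1.16 ± 0.12 (log2 ± SE, limma adjusted p = 3.22e-10). At day 6 it was 5.58 ± 0.749 and 4.97 ± 0.255, and the log2 difference of -0.13 did not pass (limma adjusted p = 0.357). In the c set Irf8 was 59 ± 1.29 in the day 0 libraries labelled cWT and 209.9 ± 4.18 in those labelled cKO, higher by 1.81 ± 0.12 (limma adjusted p = 4.12e-14). The day 3 values were 6.42 ± 0.982 and 65.4 ± 3.03, higher in the libraries labelled cKO by 3.17 ± 0.12 (limma adjusted p = 1.92e-19). At day 6 the order was the opposite, 26.3 ± 1.88 in the libraries labelled cWT and 11.2 ± 3.08 in those labelled cKO, a log2 difference of -1.20 (limma adjusted p = 1.59e-09). The authors' deposited table gave Irf8 ratios of knockout to wild type of 0.903, 2.43 and 0.898 in the g set and 3.56, 10.1 and 0.415 in the c set on days 0, 3 and 6. For the g set at day 0 the authors' q-value was 0.00233, so that small difference passed in the authors' test and not in limma. The 3 libraries of each group did not overlap there, at 61.1 to 66.3 RPKM in gWT and 56.3 to 59.0 in gKO. A gene-level RPKM also counts reads from parts of the transcript outside a deleted exon, so these values neither establish nor exclude the loss of IRF8 protein. Because Irf8 goes against the knockout label in several groups, directions below are those of the libraries labelled gKO, cWT and cKO.

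**Figure D1:**
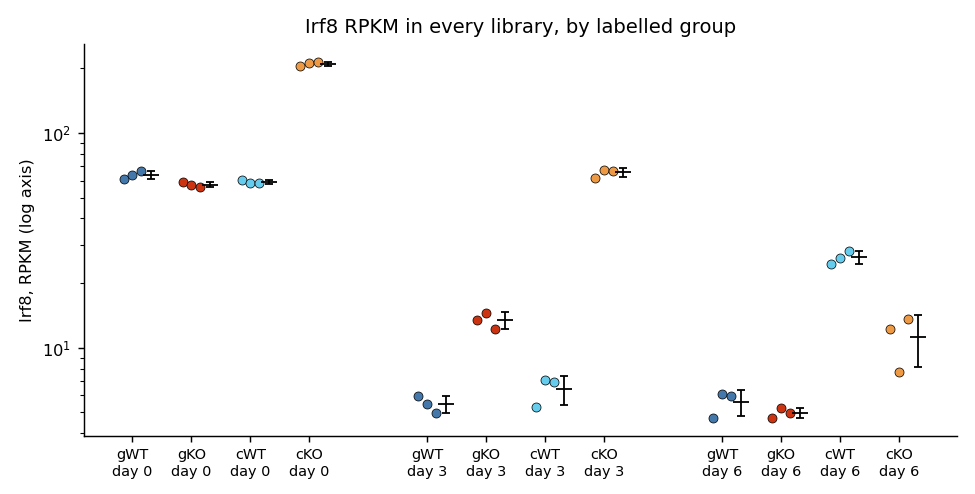
Irf8 RPKM (log axis) in each of the 36 libraries by labelled genotype and day, with points for libraries and the mean ± SD (n = 3) as a black bar beside them. The 3 libraries labelled cKO lay above those labelled cWT on days 0 and 3 and below them on day 6.

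The g and c sets differed in sex-linked genes and in sequencing data set. Xist, expressed from the inactive X chromosome, averaged 30.3 to 62.2 RPKM in the c groups and at most 0.0106 in the g groups. The Y-linked genes Ddx3y (11.3 to 16.1 RPKM) and Eif2s3y (24.3 to 32.9 RPKM) were expressed in the g groups only, and Eif2s3y was listed at 0 in every c group. The file header says that 3 data sets were combined without listing their libraries. Library names begin with s, t or u, and these letters were read as the data sets, which the sources do not state. All g libraries belonged to u. The day 0 and day 3 libraries labelled cWT belonged to s and those labelled cKO to t. At day 6 the libraries labelled cKO belonged to s, and those labelled cWT comprised 2 of t and 1 of s. Comparisons within the g set therefore lay within a single sex pattern and data set. Those between cKO and cWT crossed data sets, which could be separated only through the labelled cWT group of day 6.

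Wild-type cells were compared between days to follow the differentiation itself. In gWT cells the cathepsin K gene Ctsk, whose product degrades bone collagen, rose from 33 ± 15.7 RPKM at day 0 to 1631 ± 419.8 at day 3 (SD, n = 3), 50.3-fold on the RPKM + 1 scale. Acp5, encoding tartrate-resistant acid phosphatase, rose from 25.7 ± 9.05 to 1039 ± 263, and Mmp9, a gelatinase gene, from 35.1 ± 11.1 to 1274 ± 251. The AP-1 gene Jdp2 (log2 change 5.27 ± 0.06, SE) and the osteoclast fusion gene Ocstamp (4.71 ± 0.10) rose as well. Among the largest falls were Fcrls (-6.38 ± 0.12), the tetraspan gene Ms4a4a (-6.34 ± 0.21), the coagulation factor gene F13a1 (-5.75 ± 0.11) and the chemokine receptor gene Ccr2 (-5.28 ± 0.13). Irf8 fell by 3.32 on the log2 scale.

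Of the 24 osteoclast effector genes, 23 rose and 1 fell between day 0 and day 3 in gWT (median 3.40, limma camera adjusted p = 7.76e-08, and adjusted p = 0.255 with an estimated correlation). Of the 38 cell cycle genes, 38 rose (median 1.28, limma camera adjusted p = 1.26e-07, and adjusted p = 0.291 with an estimated correlation), led by Ccne1 (2.40), Ccne2 (2.37) and Mcm2 (2.35). For oxidative phosphorylation 43 rose and 2 did not pass (median 0.79, limma camera adjusted p = 5.73e-06, and adjusted p = 0.427 with an estimated correlation), with the cytochrome genes Cycs (2.54) and Cyc1 (2.12) in front. For glycolysis 15 rose and 4 fell (median 0.65, limma camera adjusted p = 0.0376, and adjusted p = 0.427 with an estimated correlation). Of the 45 interferon response genes, 45 fell (median -2.21, limma camera adjusted p = 1.43e-16, and adjusted p = 0.255 with an estimated correlation), with Ifit2 at -4.81, Ifit3 at -4.64 and the antiviral GTPase gene Mx1 at -3.99. Of the 33 macrophage identity genes, 1 rose, 30 fell and 2 did not pass (median -2.11, limma camera adjusted p = 7.61e-12, and adjusted p = 0.255 with an estimated correlation), among them the Fc receptor genes Fcgr1 (-5.04) and Fcgr3 (-4.43). Of the 22 monocyte genes, 2 rose, 18 fell and 2 did not pass (median -1.63, limma camera adjusted p = 7.47e-06, and adjusted p = 0.255 with an estimated correlation). For the MHC class II list 1 rose and 11 fell (median -1.18, limma camera adjusted p = 0.000764, and adjusted p = 0.255 with an estimated correlation). For the MHC class I list 2 rose, 10 fell and 6 did not pass (median -0.51, limma camera adjusted p = 0.00891, and adjusted p = 0.408 with an estimated correlation), where H2-Q7 rose (2.71) while H2-T23 fell (-2.20). For complement and opsonins 2 rose, 11 fell and 1 did not pass (median -1.39, limma camera adjusted p = 0.00149, and adjusted p = 0.255 with an estimated correlation). For cholesterol synthesis 5 rose, 14 fell and 2 did not pass (median -0.31, limma camera adjusted p = 0.035, and adjusted p = 0.335 with an estimated correlation).

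Lists of cytokines and of other cell types also moved between day 0 and day 3 in gWT. Of the inflammatory cytokine genes 5 rose, 18 fell and 2 did not pass (median -0.54, limma camera adjusted p = 0.00891, and adjusted p = 0.291 with an estimated correlation). Of the inflammasome genes 3 rose, 11 fell and 2 did not pass (median -0.83, limma camera adjusted p = 0.00417, and adjusted p = 0.255 with an estimated correlation). Neutrophil granule genes gave the lowest median of these lists, and 22 fell and 4 did not pass (median -1.86, limma camera adjusted p = 6.46e-07, and adjusted p = 0.255 with an estimated correlation). For dendritic cells 4 rose and 14 fell (median -1.22, limma camera adjusted p = 0.00111, and adjusted p = 0.255 with an estimated correlation). For lymphocytes 1 rose and 8 fell (median -1.10, limma camera adjusted p = 0.01, and adjusted p = 0.255 with an estimated correlation). For progenitors 2 rose, 9 fell and 1 did not pass (median -0.82, limma camera adjusted p = 0.01, and adjusted p = 0.255 with an estimated correlation). The mast cell, basophil and eosinophil list (2 rose, 9 fell and 1 did not pass; median -1.05, limma camera adjusted p = 0.0319, and adjusted p = 0.291 with an estimated correlation) and the erythroid and megakaryocyte list (2 rose and 6 fell; median -1.03, limma camera adjusted p = 0.0479, and adjusted p = 0.255 with an estimated correlation) no longer passed after quantile scaling (adjusted p = 0.0747 and 0.0804). No call was made for positive osteoclast regulators (15 rose, 10 fell and 4 did not pass; median 0.21, limma camera adjusted p = 0.423), negative ones (6 rose, 12 fell and 5 did not pass; median -0.29, limma camera adjusted p = 0.0573) or the V-ATPase and lysosome list (16 rose, 12 fell and 3 did not pass; median 0.13, limma camera adjusted p = 0.771). The stromal list (10 rose, 2 fell and 6 did not pass; median 0.65, limma camera adjusted p = 0.538) and the stress and immediate early list (11 rose, 9 fell and 4 did not pass; median 0.03, limma camera adjusted p = 0.679) were not called either. Counts above are over all genes tested and were identical adjusted over the list alone. The limma test called 9891 genes, 5741 higher and 4150 lower, with 1871 at least 2-fold higher and 1307 at least 2-fold lower. The median change over all genes was 0.13 as deposited and 0.02 after quantile scaling, so changes are relative to that shift. With replicate number as a block the count was 9875.

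From day 3 to day 6 the osteoclast genes went up further in gWT. Calcr, the calcitonin receptor gene, rose by 3.25 ± 0.13 (log2 ± SE) from 4.35 ± 1.06 to 49.3 ± 1.25 RPKM (SD, n = 3). Acp5 (2.66 ± 0.20), the immunoreceptor gene Oscar (2.63 ± 0.13), the metalloreductase gene Steap4 (3.65 ± 0.13) and Coq8a (3.59 ± 0.07) rose too. Ccnd1, the cyclin D1 gene, fell (-3.70 ± 0.12), as did Mybl2 (-3.21 ± 0.08) and the MHC class I genes H2-Q8 (-4.25 ± 0.24) and H2-Q7 (-3.42 ± 0.14). Of the osteoclast effector genes 24 rose (median 1.87, limma camera adjusted p = 1.1e-14, and adjusted p = 0.474 with an estimated correlation). For V-ATPase and lysosome genes 22 rose, 5 fell and 4 did not pass (median 0.70, limma camera adjusted p = 1.63e-07, and adjusted p = 0.474 with an estimated correlation), with the proton pump subunit genes Atp6v1e1 (1.75) and Atp6v1d (1.73) among the highest. For oxidative phosphorylation 43 rose and 2 did not pass (median 0.81, limma camera adjusted p = 5.94e-14, and adjusted p = 0.794 with an estimated correlation). Cell cycle genes went the other way (38 fell; median -2.19, limma camera adjusted p = 1.1e-14, and adjusted p = 0.474 with an estimated correlation), led by Ube2c (-2.80) and Mcm5 (-2.72). These 4 of the 24 lists were called, with identical counts adjusted over the list alone. Neutrophil granule genes (19 fell and 7 did not pass; median -0.84, limma camera adjusted p = 0.0554) passed after quantile scaling (adjusted p = 0.00394). In all, 8965 genes passed in limma, 3285 higher and 5680 lower, and 4511 higher against 4435 lower after quantile scaling, which moved the median of all genes from -0.14 to 0.01. As deposited, 592 were at least 2-fold higher and 1220 at least 2-fold lower.

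Osteoclast genes also rose between day 0 and day 3 in the libraries labelled cWT. Ctsk rose by 6.17 ± 0.22, Acp5 by 5.95 ± 0.20, the matrix metalloproteinase gene Mmp14 by 6.10 ± 0.11, the fusion gene Dcstamp by 5.73 ± 0.12 and the V-ATPase gene Atp6v0d2 by 5.64 ± 0.11 (log2 ± SE, n = 3). F13a1 (-6.37 ± 0.11), Fcrls (-6.06 ± 0.12), Cbr2 (-5.12 ± 0.12) and the iron exporter gene Slc40a1 (-4.89 ± 0.13) fell. Of the osteoclast effector genes 23 rose and 1 fell (median 3.16, limma camera adjusted p = 7.02e-12, and adjusted p = 0.185 with an estimated correlation). Of the oxidative phosphorylation genes 45 rose (median 1.05, limma camera adjusted p = 2.69e-11, and adjusted p = 0.396 with an estimated correlation). For macrophage identity 2 rose, 29 fell and 2 did not pass (median -2.06, limma camera adjusted p = 5.03e-10, and adjusted p = 0.185 with an estimated correlation). For monocytes 2 rose, 19 fell and 1 did not pass (median -1.49, limma camera adjusted p = 5.58e-06, and adjusted p = 0.185 with an estimated correlation). For neutrophil granules 24 fell and 2 did not pass (median -1.65, limma camera adjusted p = 5.84e-07, and adjusted p = 0.265 with an estimated correlation). Cholesterol synthesis was the only list called under both correlation settings, in this comparison alone. Of its genes 21 fell (median -1.34, limma camera adjusted p = 9.02e-10, and adjusted p = 0.0488 with an estimated correlation), with Insig1 at -1.94 and Stard4 at -1.91. For interferon response genes 24 rose, 13 fell and 8 did not pass (median 0.38, limma camera adjusted p = 0.21). For the cell cycle 9 rose, 19 fell and 10 did not pass (median -0.21, limma camera adjusted p = 0.211). The counts given so far were the same adjusted over the list alone unless a second count stands in brackets. The MHC class I list (median 0.64, limma camera adjusted p = 0.038, and adjusted p = 0.561 with an estimated correlation) lost its call after quantile scaling (adjusted p = 0.0876), and the MHC class II list (median -0.98, limma camera adjusted p = 0.0509) gained one (adjusted p = 0.0339). With limma, 9342 genes passed, 4724 higher and 4618 lower, and 1107 were at least 2-fold higher and 1099 at least 2-fold lower. All 6 libraries of this step belonged to data set s.

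Between day 3 and the day 6 libraries labelled cWT, matrix and stromal genes were among the largest rises. Mgp, encoding matrix Gla protein, rose from 1.23 ± 1.2 to 52.4 ± 21.9 RPKM (SD, n = 3), by 4.62 ± 0.43 on the log2 scale. Col6a1 (4.23 ± 0.38), the fibronectin gene Fn1 (4.19 ± 0.42), the biglycan gene Bgn (3.96 ± 0.37) and Sparc (3.83 ± 0.43) followed. Oasl1 (-2.94 ± 0.15), Pgf (-2.92 ± 0.12), Irf7 (-2.53 ± 0.20), the ubiquitin-like modifier gene Isg15 (-2.32 ± 0.18) and the complement gene C1qa (-2.23 ± 0.18) fell. Of the stromal genes 15 rose and 3 fell (median 2.30, limma camera adjusted p = 4.66e-05, and adjusted p = 0.401 with an estimated correlation). Of the osteoclast effector genes 21 rose and 3 did not pass (median 0.89, limma camera adjusted p = 6.56e-10, and adjusted p = 0.401 with an estimated correlation). For V-ATPase and lysosome genes 25 rose, 2 fell and 4 did not pass (median 0.47, limma camera adjusted p = 3.98e-08, and adjusted p = 0.401 with an estimated correlation). For cholesterol synthesis 18 rose, 1 fell and 2 did not pass (median 0.47, limma camera adjusted p = 1.85e-08, and adjusted p = 0.0864 with an estimated correlation). For macrophage identity 21 rose, 4 fell and 8 did not pass (median 0.37, limma camera adjusted p = 0.000483, and adjusted p = 0.582 with an estimated correlation). For interferon response genes 39 fell and 6 did not pass (median -0.83, limma camera adjusted p = 2.93e-07, and adjusted p = 0.582 with an estimated correlation). For MHC class I 15 fell and 3 did not pass (0 rose and 16 fell adjusted over the list alone; median -0.82, limma camera adjusted p = 6.59e-05, and adjusted p = 0.432 with an estimated correlation). For the cell cycle 37 fell and 1 did not pass (0 rose and 38 fell adjusted over the list alone; median -1.06, limma camera adjusted p = 9.8e-13, and adjusted p = 0.401 with an estimated correlation). For stress and immediate early genes 14 rose, 4 fell and 6 did not pass (median 0.48, limma camera adjusted p = 0.00368, and adjusted p = 0.401 with an estimated correlation). Where no other count stands in brackets, counts for these lists were the same adjusted over the list alone. Inflammasome (median -0.32, limma camera adjusted p = 0.212) and progenitor genes (median -0.35, limma camera adjusted p = 0.177) passed only after quantile scaling (adjusted p = 0.0469 and 0.0128). The limma test passed 8452 genes, 3377 higher and 5075 lower, with 530 at least 2-fold higher and 353 at least 2-fold lower. Irf8 rose in this step (log2 change 1.89 ± 0.12), while in gWT it differed by 0.02 with no call, and the difference between these steps was not tested. The day 6 libraries of this step may carry exchanged labels, as set out below. With the day 6 labels cWT and cKO exchanged, chosen after seeing the data, 8820 genes passed, 2918 higher and 5902 lower. Irf8 then rose by 0.69, Mgp by 3.54 and Sparc by 2.55, and C1qa rose by 1.54 where it fell by 2.23 as labelled. Within data set s, with 1 labelled cWT library at day 6, 6730 genes passed (chosen after seeing the data).

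**Figure D2:**
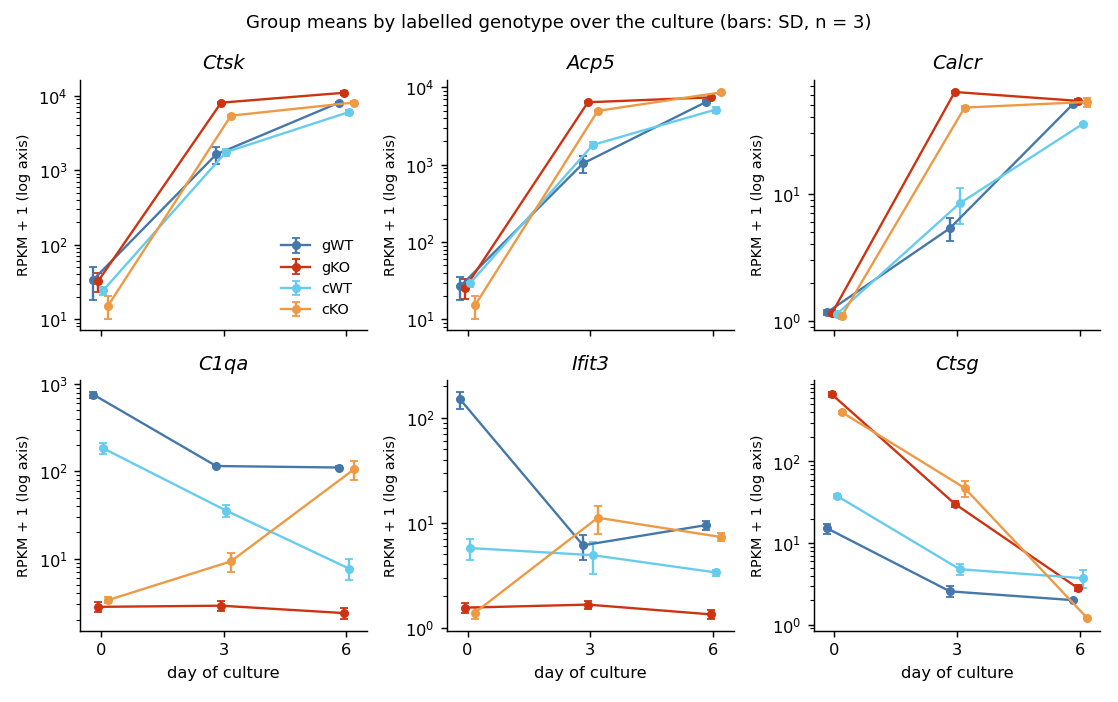
Mean RPKM + 1 (log axis) of 6 genes on days 0, 3 and 6 by labelled genotype, with SD bars (n = 3) and points set slightly apart along the day axis. Ctsk, Acp5 and Calcr were higher on day 3 than on day 0 in all 4 genotypes, and C1qa in the libraries labelled cKO was below cWT on days 0 and 3 and above it on day 6.

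The gKO and gWT cells were compared on each day to ask what changes with the Irf8 genotype at each stage. In day 0 BMMs the genes of neutrophil azurophil granules were far higher in gKO. The cathepsin G gene Ctsg rose from 14.2 ± 2.16 to 661 ± 50.9 RPKM (SD, n = 3), 43.8-fold on the RPKM + 1 scale. The myeloperoxidase gene Mpo (log2 difference 5.13 ± 0.15, SE), the neutrophil elastase gene Elane (5.12 ± 0.15), the proteinase gene Prtn3 (5.10 ± 0.15) and the chitinase-like gene Chil3 (4.59 ± 0.17) rose with it. The complement C1q genes fell steeply, C1qa from 758 ± 57.8 to 1.8 ± 0.348 RPKM (-8.09 ± 0.18), with C1qb at -7.79 and C1qc at -6.72 on the log2 scale. Ly86, which encodes the TLR-associated protein MD-1, fell from 255 ± 30.5 to 0.394 ± 0.052 RPKM. Interferon-induced genes fell as well, among them Ifit3 (-6.58 ± 0.22), Oasl2 (-5.56 ± 0.18) and the interferon regulator Irf7 (-5.32 ± 0.20).

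Of the 45 interferon response genes, 45 fell in gKO BMMs (median -3.14, limma camera adjusted p = 2.97e-25, and adjusted p = 0.189 with an estimated correlation). Of the macrophage identity genes 1 rose, 31 fell and 1 did not pass (median -1.72, limma camera adjusted p = 5.23e-13, and adjusted p = 0.189 with an estimated correlation), including Fcgr1 (-4.40), the lectin gene Clec4a1 (-3.44) and the receptor tyrosine kinase gene Axl (-3.22). Of the neutrophil granule genes 22 rose, 1 fell and 3 did not pass (median 2.11, limma camera adjusted p = 3.47e-05, and adjusted p = 0.284 with an estimated correlation). Of the cell cycle genes 38 rose (median 1.35, limma camera adjusted p = 5.64e-09, and adjusted p = 0.284 with an estimated correlation), with Rrm2 at 2.68 and Mcm2 at 2.67. For glycolysis 17 rose and 2 fell (median 0.81, limma camera adjusted p = 0.00517, and adjusted p = 0.37 with an estimated correlation). For V-ATPase and lysosome genes 2 rose, 27 fell and 2 did not pass (median -0.62, limma camera adjusted p = 1.01e-08, and adjusted p = 0.189 with an estimated correlation), the cathepsin genes Ctss (-3.27) and Ctsb (-2.01) among them. For MHC class I 2 rose and 16 fell (median -1.45, limma camera adjusted p = 7.19e-07, and adjusted p = 0.223 with an estimated correlation). For MHC class II 2 rose, 9 fell and 1 did not pass (median -1.46, limma camera adjusted p = 0.000592, and adjusted p = 0.284 with an estimated correlation). For complement and opsonins 1 rose, 12 fell and 1 did not pass (median -1.42, limma camera adjusted p = 8.58e-06, and adjusted p = 0.189 with an estimated correlation), where C3 rose (2.99). For dendritic cells 1 rose, 14 fell and 3 did not pass (median -0.80, limma camera adjusted p = 7.73e-05, and adjusted p = 0.223 with an estimated correlation). For osteoclast effectors 3 rose, 13 fell and 8 did not pass (median -0.24, limma camera adjusted p = 0.0118, and adjusted p = 0.567 with an estimated correlation). For negative osteoclast regulators 6 rose, 14 fell and 3 did not pass (median -0.36, limma camera adjusted p = 0.0159, and adjusted p = 0.284 with an estimated correlation), with Id3 at -3.58. Positive regulators (11 rose, 15 fell and 3 did not pass; median -0.20, limma camera adjusted p = 0.0402, and adjusted p = 0.284 with an estimated correlation) and erythroid and megakaryocyte genes (1 rose, 5 fell and 2 did not pass; median -0.92, limma camera adjusted p = 0.0314, and adjusted p = 0.189 with an estimated correlation) no longer passed after quantile scaling (adjusted p = 0.0614 and 0.0596). Monocyte genes (15 rose, 5 fell and 2 did not pass; median 1.03, limma camera adjusted p = 0.0612) and oxidative phosphorylation genes (22 rose, 4 fell and 19 did not pass, with 21 rose and 2 fell adjusted over the list alone; median 0.22, limma camera adjusted p = 0.442) passed only after it (adjusted p = 0.0241 and 0.0266). Other counts of the lists in this paragraph were the same adjusted over the list alone. In limma 9344 genes passed, 5809 higher and 3535 lower, 1460 of them at least 2-fold higher and 936 at least 2-fold lower. The median over all genes was 0.16 as deposited and 0.03 after quantile scaling, which gave 4839 higher and 4418 lower.

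At day 3 the pre-osteoclasts labelled gKO had higher osteoclast, monocyte and granule genes. Calcr was 62 ± 1.01 RPKM in gKO against 4.35 ± 1.06 in gWT (SD, n = 3; log2 difference 3.57 ± 0.13, SE), and Oscar (2.85 ± 0.13), Acp5 (2.66 ± 0.20) and Mmp9 (2.57 ± 0.14) were higher too. The haptoglobin gene Hp (5.11 ± 0.14), the acute phase gene Saa3 (4.98 ± 0.36), F13a1 (4.74 ± 0.11), Chil3 (4.56 ± 0.17) and the monocyte surface gene Ly6c2 (4.49 ± 0.18) were among the largest rises. The C1q genes C1qa (-5.33 ± 0.18) and C1qb (-5.22 ± 0.15), Ccnd1 (-4.92 ± 0.12), the placental growth factor gene Pgf (-4.50 ± 0.12) and H2-Q7 (-4.71 ± 0.14) were among the largest falls. Of the osteoclast effector genes 23 rose and 1 did not pass (median 1.76, limma camera adjusted p = 1.41e-11, and adjusted p = 0.311 with an estimated correlation). For V-ATPase and lysosome genes 21 rose, 7 fell and 3 did not pass (median 0.59, limma camera adjusted p = 0.000264, and adjusted p = 0.776 with an estimated correlation). For oxidative phosphorylation 38 rose and 7 did not pass (median 0.59, limma camera adjusted p = 3.81e-08, and adjusted p = 0.873 with an estimated correlation). For monocytes 16 rose, 4 fell and 2 did not pass (median 1.92, limma camera adjusted p = 1.43e-05, and adjusted p = 0.311 with an estimated correlation). For neutrophil granules 25 rose and 1 did not pass (median 2.20, limma camera adjusted p = 2e-11, and adjusted p = 0.311 with an estimated correlation), with S100a8 at 4.05 and Lcn2 at 3.65. Of the cell cycle genes 38 fell (median -1.85, limma camera adjusted p = 3.42e-12, and adjusted p = 0.486 with an estimated correlation), Tk1 (-2.78) and Mcm3 (-2.42) leading. For interferon response genes 1 rose, 40 fell and 4 did not pass (median -1.17, limma camera adjusted p = 5.49e-06, and adjusted p = 0.873 with an estimated correlation). For MHC class I 1 rose, 16 fell and 1 did not pass (median -0.68, limma camera adjusted p = 0.0108, and adjusted p = 0.873 with an estimated correlation). Positive osteoclast regulators (14 rose, 9 fell and 6 did not pass; median 0.07, limma camera adjusted p = 0.598) and macrophage identity genes (17 rose, 9 fell and 7 did not pass; median 0.23, limma camera adjusted p = 0.32) were not called. For the lists given here, counts did not change adjusted over the list alone unless a second count is given. With limma 9384 genes passed, 3862 higher and 5522 lower, 804 at least 2-fold higher and 1305 at least 2-fold lower, and 4731 higher against 4662 lower after quantile scaling, which moved the median of all genes from -0.11 to -0.01. With replicate number as a block the count was 9369.

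At day 6 granule genes were higher and interferon and complement C1q genes lower in gKO osteoclasts. S100a9 (3.29 ± 0.19), S100a8 (3.13 ± 0.20), Lcn2 (3.02 ± 0.20) and the lactoferrin gene Ltf (2.83 ± 0.19) were among the largest rises in gKO (log2 ± SE, n = 3). C1qb (-5.61 ± 0.15), C1qa (-5.55 ± 0.18), Ly86 (-3.01 ± 0.13), Oasl2 (-2.97 ± 0.18) and Ifit3 (-2.83 ± 0.22) were among the largest falls, C1qa being 109.7 ± 5.08 RPKM in gWT and 1.37 ± 0.365 in gKO. Of the neutrophil granule genes 23 rose and 3 did not pass (median 0.91, limma camera adjusted p = 8.71e-12, and adjusted p = 0.133 with an estimated correlation). For interferon response genes 45 fell (median -1.50, limma camera adjusted p = 1.73e-28, and adjusted p = 0.133 with an estimated correlation). For MHC class I 16 fell and 2 did not pass (median -0.78, limma camera adjusted p = 3.76e-10, and adjusted p = 0.134 with an estimated correlation). For MHC class II 9 fell and 3 did not pass (median -0.93, limma camera adjusted p = 8.75e-06, and adjusted p = 0.196 with an estimated correlation), with H2-Ab1 at -1.62. For cholesterol synthesis 16 rose and 5 did not pass (median 0.33, limma camera adjusted p = 3.34e-08, and adjusted p = 0.104 with an estimated correlation), Idi1 (0.95) and Sqle (0.93) in front. For the cell cycle 22 rose, 1 fell and 15 did not pass (24 rose and 1 fell adjusted over the list alone; median 0.24, limma camera adjusted p = 5.68e-05, and adjusted p = 0.599 with an estimated correlation). For monocytes 10 rose, 4 fell and 8 did not pass (14 rose and 4 fell adjusted over the list alone; median 0.29, limma camera adjusted p = 0.00486, and adjusted p = 0.564 with an estimated correlation). For oxidative phosphorylation 27 fell and 18 did not pass (median -0.30, limma camera adjusted p = 1.01e-05, and adjusted p = 0.656 with an estimated correlation). For macrophage identity 3 rose, 21 fell and 9 did not pass (median -0.44, limma camera adjusted p = 0.000161, and adjusted p = 0.599 with an estimated correlation). For inflammasomes 4 rose, 10 fell and 2 did not pass (4 rose and 11 fell adjusted over the list alone; median -0.23, limma camera adjusted p = 0.0295, and adjusted p = 0.599 with an estimated correlation). Osteoclast effector genes were not called as a list (4 rose, 7 fell and 13 did not pass; median -0.05, limma camera adjusted p = 0.454), nor were stromal genes (3 rose, 2 fell and 13 did not pass, with 0 rose and 2 fell adjusted over the list alone; median 0.29, limma camera adjusted p = 0.438). Other counts of the lists given here equalled those adjusted over the list alone. In limma 5932 genes passed, 2935 higher and 2997 lower (3314 and 2839 after quantile scaling), and 81 were at least 2-fold higher and 201 at least 2-fold lower.

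The same question was put to the c set, in which data set and label could not be told apart on days 0 and 3 without the labelled day 6 groups. In BMMs labelled cKO, Chil3 rose from 88.4 ± 0.964 to 1577 ± 56 RPKM (SD, n = 3; log2 difference 4.14 ± 0.17, SE). Ms4a3 (3.45 ± 0.15), Ctsg (3.40 ± 0.14), Elane (3.37 ± 0.15) and Prtn3 (3.35 ± 0.15) were higher as well. Ly86 (-5.84 ± 0.13), C1qa (-5.77 ± 0.18), C1qb (-5.08 ± 0.15) and the interferon-inducible gene Ifi202b (-4.41 ± 0.09) were lower. Of the neutrophil granule genes 25 rose and 1 fell (median 2.14, limma camera adjusted p = 2.64e-10, and adjusted p = 0.373 with an estimated correlation). Of the monocyte genes 15 rose, 4 fell and 3 did not pass (median 1.17, limma camera adjusted p = 0.0143, and adjusted p = 0.471 with an estimated correlation). Of the 9 lymphocyte genes 6 rose, 1 fell and 2 did not pass (median 1.42, limma camera adjusted p = 0.0143, and adjusted p = 0.421 with an estimated correlation), with the B cell receptor gene Cd79a at 2.55 and the pre-B cell gene Vpreb3 at 2.21. For glycolysis 15 rose, 2 fell and 2 did not pass (median 0.24, limma camera adjusted p = 0.0158, and adjusted p = 0.58 with an estimated correlation). For the cell cycle 23 rose, 2 fell and 13 did not pass (median 0.26, limma camera adjusted p = 0.0104, and adjusted p = 0.657 with an estimated correlation). For interferon response genes 38 fell and 7 did not pass (median -0.94, limma camera adjusted p = 9.06e-10, and adjusted p = 0.424 with an estimated correlation). For macrophage identity 3 rose, 27 fell and 3 did not pass (median -0.90, limma camera adjusted p = 4.24e-08, and adjusted p = 0.386 with an estimated correlation). For MHC class II 1 rose, 10 fell and 1 did not pass (median -1.33, limma camera adjusted p = 8.83e-05, and adjusted p = 0.386 with an estimated correlation). For dendritic cells 5 rose, 11 fell and 2 did not pass (median -0.64, limma camera adjusted p = 0.00165, and adjusted p = 0.421 with an estimated correlation). For complement 2 rose, 9 fell and 3 did not pass (median -0.65, limma camera adjusted p = 0.00484, and adjusted p = 0.424 with an estimated correlation). For V-ATPase and lysosome genes 2 rose, 24 fell and 5 did not pass (median -0.33, limma camera adjusted p = 3.47e-05, and adjusted p = 0.421 with an estimated correlation). For cholesterol synthesis 2 rose, 18 fell and 1 did not pass (median -0.47, limma camera adjusted p = 8.83e-05, and adjusted p = 0.373 with an estimated correlation). For these lists, counts without a second count in brackets were identical adjusted over the list alone. In limma 8063 genes passed, 4298 higher and 3765 lower (3954 and 4157 after quantile scaling, so the majority turned), 501 at least 2-fold higher and 371 at least 2-fold lower. With data set as a term, chosen after seeing the data, 5112 passed, and 870 of the 872 genes at least 2-fold apart kept their sign. That term rests on 2 t libraries and 1 s library of labelled cWT at day 6.

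Pre-osteoclasts labelled cKO had higher osteoclast effector genes than those labelled cWT at day 3. Calcr was 46.5 ± 0.983 RPKM against 7.41 ± 2.66 (SD, n = 3; log2 difference 2.55 ± 0.13, SE), and Oscar (2.15 ± 0.13), Siglec15 (2.03 ± 0.15) and Tspan7 (1.88 ± 0.12) were higher too. Saa3 (4.47 ± 0.36), F13a1 (4.45 ± 0.11), Chil3 (4.28 ± 0.17), Hp (4.19 ± 0.14) and Ms4a4a (4.15 ± 0.21) were among the largest rises. Pgf (-4.15 ± 0.12), Ccnd1 (-3.20 ± 0.12), the Langerhans cell lectin gene Cd207 (-3.03 ± 0.11) and H2-Q7 (-2.88 ± 0.14) were among the largest falls. Of the osteoclast effector genes 23 rose and 1 did not pass (median 1.13, limma camera adjusted p = 3.57e-10, and adjusted p = 0.325 with an estimated correlation). Of the V-ATPase and lysosome genes 23 rose, 2 fell and 6 did not pass (median 0.36, limma camera adjusted p = 5.29e-05, and adjusted p = 0.44 with an estimated correlation). For monocytes 18 rose, 3 fell and 1 did not pass (median 1.85, limma camera adjusted p = 4.18e-07, and adjusted p = 0.196 with an estimated correlation). For neutrophil granules 24 rose, 1 fell and 1 did not pass (median 1.72, limma camera adjusted p = 3.57e-10, and adjusted p = 0.196 with an estimated correlation). For macrophage identity 25 rose, 4 fell and 4 did not pass (median 0.67, limma camera adjusted p = 1.2e-05, and adjusted p = 0.44 with an estimated correlation). For cholesterol synthesis 15 rose, 1 fell and 5 did not pass (median 0.51, limma camera adjusted p = 1.44e-05, and adjusted p = 0.196 with an estimated correlation). Of the cell cycle genes 37 fell and 1 did not pass (median -1.31, limma camera adjusted p = 1.28e-11, and adjusted p = 0.423 with an estimated correlation). For MHC class I 15 fell and 3 did not pass (median -0.64, limma camera adjusted p = 0.00501, and adjusted p = 0.765 with an estimated correlation). The interferon response list was not called (13 rose, 20 fell and 12 did not pass; median -0.11, limma camera adjusted p = 0.663). The oxidative phosphorylation list (5 rose, 19 fell and 21 did not pass, with 5 rose and 14 fell adjusted over the list alone; median -0.14, limma camera adjusted p = 0.865) passed as higher after quantile scaling (median 0.17, adjusted p = 0.0214). Other counts of lists given here were the same adjusted over the list alone, unless a second count follows them. With limma 9134 genes passed, 3895 higher and 5239 lower, 611 at least 2-fold higher and 794 at least 2-fold lower. With data set as a term, chosen after seeing the data, 6602 passed.

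At day 6 most differences between the libraries labelled cKO and cWT ran against those of day 0, with no such relation to day 3 (r = -0.575 and -0.0578 across genes). Of 4699 genes called on days 0 and 6, 734 kept their direction, and of 5093 called on days 3 and 6, 3213 did (2788 of 4518 after quantile scaling). In gKO against gWT these were 3924 of 4976 and 1740 of 5048. Of 244 genes at least 2-fold apart in one direction on days 0 and 3, 11 kept it at day 6, against 330 of 362 in the g set. C1qa was 104 ± 26.4 RPKM in those labelled cKO and 6.7 ± 2.09 in those labelled cWT (SD, n = 3; log2 difference 3.77 ± 0.18, SE), and C1qb (3.57 ± 0.15), Ly86 (3.06 ± 0.13) and C1qc (2.86 ± 0.16) were higher too. Chil3 (-3.42 ± 0.17), F13a1 (-2.49 ± 0.11), Hp (-2.43 ± 0.14), the fractalkine receptor gene Cx3cr1 (-2.41 ± 0.12) and S100a8 (-2.30 ± 0.20) were lower. Of the neutrophil granule genes 25 fell and 1 did not pass (median -1.48, limma camera adjusted p = 2.2e-10, and adjusted p = 0.226 with an estimated correlation). Of the cell cycle genes 38 fell (median -1.01, limma camera adjusted p = 4.43e-19, and adjusted p = 0.226 with an estimated correlation), with Mki67 at -1.63 and Top2a at -1.35. For monocytes 2 rose, 18 fell and 2 did not pass (2 rose and 20 fell adjusted over the list alone; median -0.70, limma camera adjusted p = 2.24e-05, and adjusted p = 0.226 with an estimated correlation). For interferon response genes 35 rose, 1 fell and 9 did not pass (36 rose and 1 fell adjusted over the list alone; median 0.49, limma camera adjusted p = 8.01e-17, and adjusted p = 0.226 with an estimated correlation). For osteoclast effectors 18 rose, 1 fell and 5 did not pass (19 rose and 2 fell adjusted over the list alone; median 0.35 where the g set had -0.05, limma camera adjusted p = 3.72e-09, and adjusted p = 0.226 with an estimated correlation), with Rab38 at 0.98 and Oscar at 0.94. Of the V-ATPase and lysosome genes 21 rose and 10 did not pass (23 rose and 1 fell adjusted over the list alone; median 0.33, limma camera adjusted p = 6.89e-15, and adjusted p = 0.171 with an estimated correlation). For MHC class II 7 rose, 1 fell and 4 did not pass (median 0.40, limma camera adjusted p = 8.74e-05, and adjusted p = 0.226 with an estimated correlation). For MHC class I 10 rose, 2 fell and 6 did not pass (11 rose and 2 fell adjusted over the list alone; median 0.25, limma camera adjusted p = 7.4e-05, and adjusted p = 0.336 with an estimated correlation). For complement 5 rose, 2 fell and 7 did not pass (median 0.17, limma camera adjusted p = 2.24e-05, and adjusted p = 0.226 with an estimated correlation). For macrophage identity 14 rose, 5 fell and 14 did not pass (median 0.20, limma camera adjusted p = 1.72e-05, and adjusted p = 0.336 with an estimated correlation). For oxidative phosphorylation 15 rose and 30 did not pass (7 rose and 0 fell adjusted over the list alone; median 0.17, limma camera adjusted p = 1.12e-07, and adjusted p = 0.518 with an estimated correlation). Dendritic cell genes (5 rose, 4 fell and 9 did not pass; median 0.08, limma camera adjusted p = 0.0326, and adjusted p = 0.518 with an estimated correlation) lost their call after quantile scaling (adjusted p = 0.0869), and stromal genes (2 rose, 11 fell and 5 did not pass, with 2 rose and 12 fell adjusted over the list alone; median -1.01, limma camera adjusted p = 0.193) gained one (adjusted p = 0.0144), as did glycolysis genes (2 rose, 14 fell and 3 did not pass; median -0.25, limma camera adjusted p = 0.0678; adjusted p = 0.00053 after scaling). The osteoclast effector, V-ATPase and lysosome, macrophage identity and cell cycle lists thus kept their day 3 direction. Lists given here without a second count had the same count adjusted over the list alone.

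In this day 6 comparison 6357 genes passed in limma, 1569 higher and 4788 lower in the libraries labelled cKO, 70 at least 2-fold higher and 197 at least 2-fold lower. After quantile scaling, which moved the median of all genes from -0.11 to 0.01, 3003 were higher and 2756 lower. Fitted on these 2 groups alone, 4165 genes passed. Within data set s, with 3 libraries labelled cKO and 1 labelled cWT (chosen after seeing the data), 4021 passed, 825 higher and 3196 lower. That fit assumes that the single cWT library varies like the other groups.

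**Figure D3:**
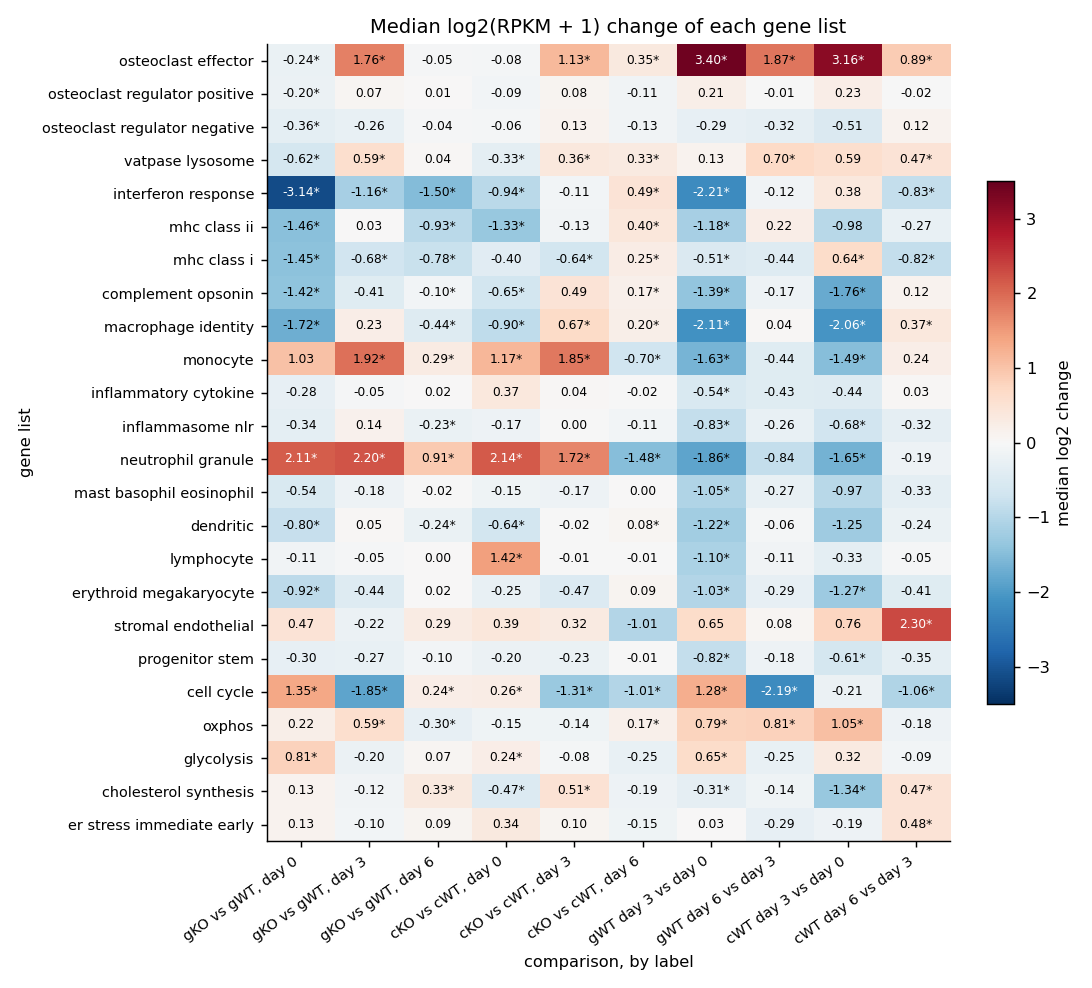
Median log2(RPKM + 1) change of the 24 gene lists (vertical) in 10 comparisons by label (horizontal), from blue for lower to red for higher, with an asterisk where the list passed limma camera at an adjusted p below 0.05 with its preset correlation. The neutrophil granule list was at 2.14, 1.72 and -1.48 in cKO against cWT on days 0, 3 and 6, and only cholesterol synthesis in cWT day 3 against day 0 also passed with an estimated correlation.

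Whether the g and c sets changed alike was asked gene by gene, and the groups compared share no library. On day 0, 7024 genes passed in both sets, 6580 in the same direction and 444 in opposite ones. Higher in both were 3823 genes where independent lists would share 2104.6 (odds ratio 22.6, Fisher's exact test), and lower in both were 2757 where 1121.9 would be shared (odds ratio 25.7). Of the 710 genes at least 2-fold apart in both sets, 705 went the same way, Ctsg, Chil3, C1qa and Ly86 among them. On day 3, 6955 genes changed the same way and 635 opposite, with odds ratios of 14.4 for the higher and 16.8 for the lower genes. Of 1057 genes at least 2-fold apart in both, 1056 went the same way. On day 6 the count with the same direction was 612, and 3013 genes went opposite ways. Higher in gKO and lower in the libraries labelled cKO were 2027 genes where 1184.6 would be shared (odds ratio 4.99), and 986 genes went the reverse way where 396.4 would be (odds ratio 6.96). All 76 genes at least 2-fold apart in both sets went opposite ways. Sharing in the same direction lay below that of independent lists, with 133 higher in both where 388.2 would be shared (odds ratio 0.248) and 479 lower where 1209.6 would be (odds ratio 0.201). Across genes, which are not independent replicates, the log2 differences of the sets correlated at r = 0.809 on day 0, 0.814 on day 3 and -0.577 on day 6. After quantile scaling the shared day 6 genes were 337 higher and 203 lower. With data set as a term, chosen after seeing the data, the count of shared day 6 genes was 360.

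**Figure D4:**
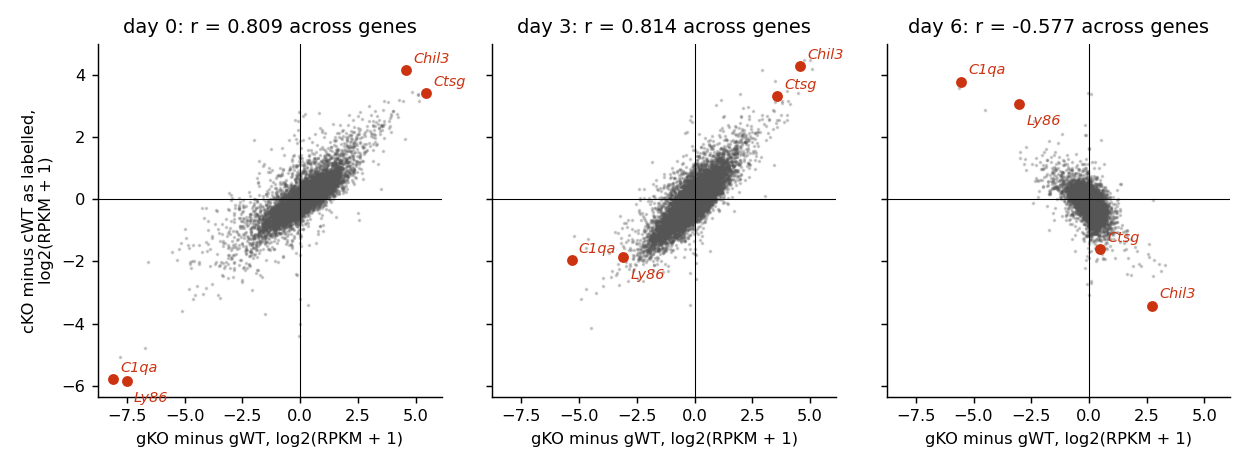
Log2(RPKM + 1) difference of gKO from gWT (horizontal) against that of cKO from cWT as labelled (vertical) for the 11863 genes tested on days 0, 3 and 6, with 4 genes marked in red. The cloud rises on days 0 and 3 (r = 0.809 and 0.814 across genes) and falls on day 6 (r = -0.577).

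Each c library was also set against the gKO minus gWT difference of its own day. On days 0 and 3 all 6 libraries of each day lay on the side of their label. At day 6 all 6 lay on the other side, the 3 labelled cWT with gKO (r across genes 0.486, 0.53 and 0.492) and the 3 labelled cKO with gWT (r = -0.462, -0.442 and -0.519). The labelled cWT library of data set s lay with the pair of data set t. A header line says that the annotation of the day 6 c libraries had been corrected.

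**Figure D5:**
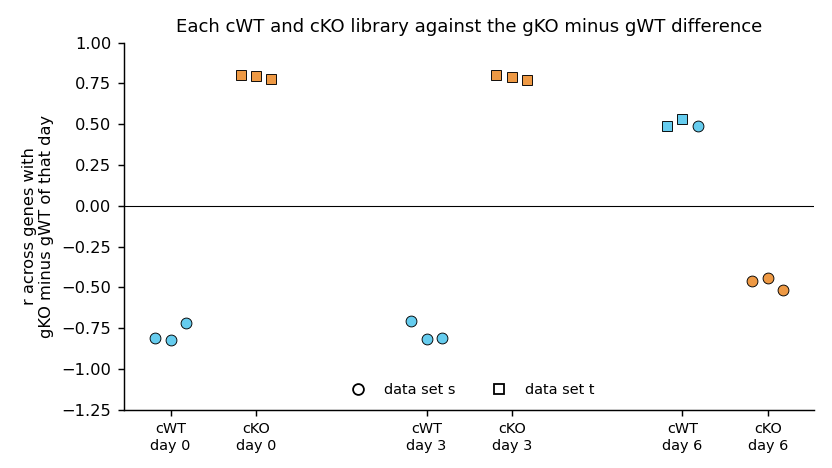
Correlation across genes (vertical, no unit) of each c library, relative to the mean of the 6 c libraries of its day, with the gKO minus gWT difference of that day, as circles for data set s and squares for data set t. The libraries labelled cKO lie above 0 on days 0 and 3 and below 0 on day 6.

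Interaction terms tested whether the genotype differences themselves differed between days. For gKO against gWT, the difference at day 6 minus that at day 0 passed for 8404 genes in limma, 2931 higher and 5473 lower. Ly86 (4.50 ± 0.19, log2 ± SE) and Ifit3 (3.76 ± 0.31) were among the highest, and Ctsg (-4.96 ± 0.20) and Mpo (-4.83 ± 0.21) among the lowest. After quantile scaling the split was 3906 higher and 4231 lower, and the median of all genes moved from -0.18 to -0.02. For the libraries labelled cKO and cWT, 8431 genes passed, 3211 higher and 5220 lower, and 4347 and 4160 after quantile scaling, which moved the median from -0.13 to 0.02. C1qa (9.55 ± 0.26), Ly86 (8.90 ± 0.19) and C1qb (8.66 ± 0.22) were highest, and Chil3 (-7.56 ± 0.23) and S100a8 (-5.42 ± 0.28) lowest. Of the neutrophil granule genes 26 fell in this term (median -3.60, limma camera adjusted p = 1.77e-11, and adjusted p = 0.316 with an estimated correlation). These large values rest on the day 6 libraries as labelled, all 6 of which lay on the other genotype's side. With the day 6 labels cWT and cKO exchanged, chosen after seeing the data, 6059 genes passed, 3917 higher and 2142 lower. C1qa was then at 2.0, Ly86 at 2.77, C1qb at 1.51, Chil3 at -0.72 and S100a8 at -0.81. With data set as a term, also chosen after seeing the data, 4865 genes passed.

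The difference in gKO minus that in the libraries labelled cKO was tested on each day, across sets that also differ in sex-linked genes (Xist 62.2 RPKM in cKO and 0.0092 in gKO at day 0) and in data set. At day 0, 6798 genes passed in limma, 4723 higher and 2075 lower, and 3482 and 2774 after quantile scaling, which moved the median from 0.14 to 0.03. Ifi202b (4.37 ± 0.12) was highest and Ifit3 (-4.56 ± 0.31) lowest (log2 ± SE). Of the interferon response genes 45 fell in this term (median -2.11, limma camera adjusted p = 1.47e-40, and adjusted p = 0.0921 with an estimated correlation), with gWT BMMs at 149 ± 27.2 RPKM of Ifit3 and cWT BMMs at 4.73 ± 1.3 (SD, n = 3). Of the cell cycle genes 38 rose (median 1.12, limma camera adjusted p = 3.32e-13, and adjusted p = 0.135 with an estimated correlation). At day 3, 6511 genes passed, 2835 higher and 3676 lower (3397 and 3059 after quantile scaling, so the majority turned), with Hist1h2ak (3.20 ± 0.28) highest and C1qb (-4.02 ± 0.22) lowest. Of the oxidative phosphorylation genes 45 rose (median 0.72, limma camera adjusted p = 1.09e-16, and adjusted p = 0.565 with an estimated correlation). With data set as a term, chosen after seeing the data, 3100 passed at day 3. At day 6, 7181 genes passed, 4574 higher and 2607 lower (3659 and 3456 after quantile scaling, with the median going from 0.11 to 0.01), Chil3 (6.18 ± 0.23) and S100a8 (5.43 ± 0.28) being highest and C1qa (-9.33 ± 0.26) and C1qb (-9.19 ± 0.22) lowest. With the day 6 labels cWT and cKO exchanged, chosen after seeing the data, 4560 genes passed, 983 higher and 3577 lower. Chil3 was then at -0.67, S100a8 at 0.83, C1qa at -1.78 and C1qb at -2.04. Values for H2-Q7, H2-Q8, Hist1h2ak, Ifit3, Ifi202b and Ly6c2 are uncertain to the extent that reads of near-identical family members were divided between them.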

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

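All tests of explanations in this part, and the exchange of labels, were chosen only after the result was seen, except the one on scaling of Irf8 and the splits of the libraries.

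The differences between genotypes were themselves different between days or between the g and c sets, by interaction terms in limma. In gKO against gWT, 8404 genes differed in effect between day 6 and day 0, with Ly86 at 4.50 and Ctsg at -4.96 (log2 difference of differences). In the libraries labelled cKO and cWT, 8431 genes did, with C1qa at 9.55 and Chil3 at -7.56, but with the day 6 labels cWT and cKO exchanged 6059 did, with C1qa at 2.0 and Chil3 at -0.72. Between gKO and cKO effects 6798 genes differed at day 0, with Ifi202b at 4.37 and Ifit3 at -4.56. At day 3 there were 6511, with Hist1h2ak at 3.20 and C1qb at -4.02. At day 6 there were 7181, with Chil3 at 6.18 and C1qa at -9.33, and 4560 with those labels exchanged, Chil3 at -0.67 and C1qa at -1.78.

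Most day 6 differences between libraries labelled cKO and cWT ran opposite to those of day 0 and to those of gKO and gWT. Of 244 genes at least 2-fold apart in one direction on days 0 and 3, 11 kept it (330 of 362 in the g set). Of 5093 called on days 3 and 6, 3213 kept theirs (r = -0.0578 across all genes, and 1740 of 5048 in the g set). Osteoclast effectors (median 1.13 and 0.35), V-ATPase and lysosome (0.36 and 0.33), macrophage identity (0.67 and 0.20) and cell cycle (-1.31 and -1.01) did too. The other lists called on both days (neutrophil granules, monocytes, MHC class I) turned. A turnover of the Irf8-dependent difference alone stays open. Its test took 15 of the 244 genes, those within 0.25 log2 in the g set on each day. Their median signed log2 difference at day 6 was -1.15 (-1.16 within data set s). Most were barely expressed in every g group, which leaves their dependence on Irf8 unknown. A difference between data sets s and t would turn the same genes, since cKO is t on days 0 and 3 and s at day 6, and it cannot be told apart, because the median of -0.71 for the 244 genes within data set s (-0.74 over all 6 libraries) rests on 1 cWT library. A candidate explanation, an exchange of the day 6 c labels, meets its test. Of those 15 genes 0 kept their direction (1 within data set s alone), and all 6 libraries lay on the other genotype's side. Lists that had kept their day 3 direction would then turn. In the g set osteoclast effectors (1.76 and -0.05), macrophage identity (0.23 and -0.44) and cell cycle turned too. V-ATPase and lysosome (0.59 and 0.04) did not. An exchange before or after the correction in the file header cannot be told apart, and it remains a hypothesis.

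The cKO and cWT libraries of days 0 and 3 belong to different data sets, t and s. A difference between data sets as the whole cause is argued against by the correlation of their differences with those of gKO and gWT, whose lower r across genes was 0.809. For 48 genes apart in the c set on day 0 with no difference in the g set, the t minus s difference within labelled cWT at day 6 was -0.000308 of their day 0 difference (median). Data set and genotype cannot be told apart for those genes, because that group holds 1 library of data set s. Part of their differences may come from the data set.

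Irf8 RPKM did not pass in limma as lower in gKO on days 0 and 6 (the authors' q-value at day 0 was 0.00233), and it was higher in gKO at day 3 and in the libraries labelled cKO on days 0 and 3. A raised stretch of the genome around Irf8 is argued against by the 10 nearest genes tested, with a median log2 difference of -0.12 at day 3 (-1.95 to 1.14). Scaling between libraries is argued against by the Irf8 difference of 3.30 at day 3 after quantile normalization. Transcript from outside a deleted part of Irf8, which may be raised when the protein is missing, stays open and could not be tested with a value per gene, as does a biological difference between the genotypes.

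The libraries of each comparison were also split in other ways. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The labelled split called 9344, 9384 and 5932 genes in gKO against gWT on days 0, 3 and 6, and the highest other split 2, 0 and 1. In cKO against cWT these were 8063, 9134 and 6357 against 1, 4 and 1550. In gWT they were 9891 and 8965 against 0 and 0, and in cWT 9342 and 8452 against 1 and 2941. In each of these, 1 split of 10 was as large, the labelled one. For the differences of differences 100 splits were drawn. As large were 3 of 100 for gKO day 6 minus day 0 (highest other 9153). As deposited, 1 of 100 was for cKO day 6 minus day 0 (highest other 6799) and gKO minus cKO at day 6 (5342). With the day 6 labels exchanged, 2 of 100 splits were as large as the 4560 of the second and 5 as large as the 6059 of the first, among them the labelled split, the exchange itself and 3 that left one pair of groups as labelled. For gKO minus cKO, 9 of 100 were at day 0 (highest other 9649) and 14 of 100 at day 3 (highest other 9852). All other splits as large (8 and 13 here, 2 for gKO day 6 minus day 0) had left one pair of groups as labelled. Most other splits mixed both pairs (median 0 genes), so the shares do not show whether a difference itself changed. For the genes changed the same way in both sets, 6580, 6955 and 612 on days 0, 3 and 6 stood against the highest other of 444, 635 and 413 (each 1 of 100). These splits say little on sharing, which needs calls in both sets. Other splits of one set alone called few genes, except 1550 in the c set at day 6. The 444 and 635 come from the exchange of the c labels, which was not drawn for day 6 and gave 3013 there. Overlaps lay above those of independent lists on days 0 and 3 and below them at day 6.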

How the results depend on the processing

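Data set as a term, data set s alone, exchanged labels and fits without the day 6 c libraries were chosen after the result was seen. The others were chosen before the data were examined. Across the 18 gene counts, the pseudocount, both filters, quantile scaling, the replicate block and each left-out library kept every count within 1.5 times the reported one. Fitted on its groups alone, cKO against cWT at day 6 gave 4165 genes where 6357 were reported. With data set as a term, cKO against cWT gave 5112 at day 0 (8063 reported) and 4075 at day 6. Of genes at least 2-fold apart 870 of 872, 1404 of 1405 and 267 of 267 kept their sign on days 0, 3 and 6. The cKO effect at day 6 minus day 0 gave 4865 (8431 reported) and gKO minus cKO at day 3 gave 3100 (6511 reported). Genes changed the same way at day 6 numbered 360 (612 reported). Within data set s at day 6, cKO against cWT gave 4021, and 354 genes changed the same way. Those 2 kinds of fit compare fewer samples, since s and t meet only in labelled cWT at day 6. With the day 6 labels cWT and cKO exchanged, gKO minus cKO at day 6 gave 4560 genes (7181 reported) and 3013 changed the same way at day 6 (612 reported), because those libraries enter with the opposite sign. The same exchange gave 8820 genes for cWT day 6 against day 3 and 6059 for the cKO effect at day 6 minus day 0. Without the 6 doubted day 6 libraries, gKO against gWT gave 9485, 9531 and 6232 genes, cKO against cWT gave 8275 and 9265, gWT gave 10003 and 9136, and cWT day 3 against day 0 gave 9466. The gKO effect at day 6 minus day 0 then gave 8603, gKO minus cKO 7065 and 6817, and genes changed the same way numbered 6738 and 7066 on days 0 and 3. With an estimated correlation 0 of the 24 gene lists were called in 14 contrasts, where 4 to 19 had been, and 1 (cholesterol synthesis) in cWT day 3 against day 0, where 11 had been. That setting allows for genes of a list moving together. The log2 change of Eif2s3y, gWT day 6 vs day 3, was -0.11 as reported and 0.0815 after quantile scaling, and the cause was not tested.

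Of 1215 named gene and list values, quantile scaling left 1181 on the same side of the threshold with the same direction, 21 weaker, 7 stronger, 5 moved and 1 reversed. Of the gene values alone, the pseudocount of 0.1 left 1030 the same and 6 weaker, and the estimated correlation made 178 list calls weaker. The replicate numbers pair the samples in gKO against gWT at day 3 and gWT day 3 against day 0, where the block gave 9369 and 9875 genes. In the other contrasts the correlations of same-numbered libraries ran from -0.466 to 0.47, and pairing was not shown. With the block gKO against gWT at day 0 gave 9324 genes, 1214 named values stayed the same, 1 was weaker, and the number of lists called went from 4 to 5 in gWT day 6 against day 3, from 11 to 13 in cWT day 3 against day 0, from 14 to 15 in the cKO effect at day 6 minus day 0 and from 9 to 10 in gKO minus cKO at day 3.

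With each library left out in turn, gKO against gWT gave 9020 to 9153, 9025 to 9140 and 5204 to 5601 genes on days 0, 3 and 6, and cKO against cWT gave 7523 to 7773, 8631 to 9142 and 5503 to 6328. The steps in gWT gave 9597 to 9659 and 8577 to 8728, and those in cWT 8959 to 9275 and 7855 to 8514. The effect at day 6 minus day 0 gave 8112 to 8301 for gKO and 8103 to 8487 for cKO, and gKO minus cKO gave 6401 to 6715, 5805 to 6842 and 6783 to 7256. Genes changed the same way numbered 6208 to 6551, 6732 to 6960 and 499 to 638. Among single named values in these fits 6429 stayed the same, 52 were weaker, 19 stronger and 16 moved.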

Other observations

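The values in this part were chosen only after the results were seen, and no explanation was tested for them. Stromal genes named here had their highest day 6 mean in the libraries labelled cWT. Mgp averaged 52.4 ± 21.9 RPKM (SD, n = 3) in the libraries labelled cWT and 3.59 ± 2.21 in gWT, 3.84 ± 1.1 in gKO and 25 ± 14.2 in those labelled cKO. The collagen gene Col1a2 was at 68.8 ± 7.82, 9.8 ± 6.95, 15.7 ± 5.04 and 26.7 ± 11.7 in the same order, and Sparc at 79.7 ± 11.8, 12.5 ± 8.14, 18.2 ± 5.96 and 32.5 ± 7.24.

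Calcr reached 62 ± 1.01 RPKM in gKO at day 3 and 52.7 ± 2.23 at day 6, beside 4.35 ± 1.06 and 49.3 ± 1.25 in gWT (SD, n = 3). Oscar was at 215 ± 4.55 and 165 ± 4.92 in gKO and at 29.5 ± 7.79 and 184 ± 4.93 in gWT on those days. Day 6 against day 3 was not tested within gKO. In the gKO effect at day 6 minus day 0, of the interferon response genes 44 rose and 1 did not pass (median 1.56, limma camera adjusted p = 7.94e-20, and adjusted p = 0.205 with an estimated correlation), and of the macrophage identity genes 31 rose and 2 did not pass (median 1.28, limma camera adjusted p = 3.33e-12, and adjusted p = 0.181 with an estimated correlation). In the same term of the cell cycle list 37 fell and 1 did not pass (median -1.15, limma camera adjusted p = 6.47e-08, and adjusted p = 0.413 with an estimated correlation). The interferon response genes were lower in gKO on both days, so their rise in this term marks a smaller difference and does not show a rise in gKO.

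The authors' deposited table for each day listed 11802, 11413 and 5674 genes with a q-value under 0.05 for gKO against gWT and 10753, 11473 and 6753 for cKO against cWT, out of 24950. Between the t and s libraries of labelled cWT at day 6, 13 of 11863 genes were at least 2-fold apart.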
